A study of Mus musculus with 8 samples.

How the data were processed

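The data were UMI counts per gene and cell barcode for 8 libraries of CD45-selected mouse lung cells, made with the 10x Genomics 3' kit v3.1, per the labels. The counts were deposited as a matrix, a barcode list and a gene list per library, made by the authors with Cell Ranger 6.1.1 against mm10, per the submitters' processing notes. No normalization of these counts is recorded, and every value was a whole number. The barcodes had already been restricted, since the fewest UMIs per barcode were 500 or 501 in each library. Of the 32285 features, 32158 (99.6%) had an identifier in GENCODE vM21, from which gene positions and types were taken.

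The groups came from the labels: PBS, GMPMA, GMPMA_1FP and GMPMA_3FP, with 2 libraries each and 2 mouse lungs pooled per library. The tests, the samples in each fit, the cell type markers, the gene lists, the rule for named genes and most alternatives were set before the data were examined. Cells with at least 200 genes, at least 500 UMIs and under 10% mitochondrial UMIs were kept. Scrublet, as run in scanpy with an expected rate of 0.08, scored doublets in each library. Its automatic threshold called 0 cells in 5 libraries and 2.67% to 3.34% in the other 3. After this was seen, the highest scores were called instead, at a rate in proportion to the number of barcodes, which gave 4.81% to 8.04% of cells. Clusters with at least 25% of cells called were set aside as mixed, and called doublets were left out.

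Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, 20 neighbors and the Leiden method at resolution 1 gave the clusters, with a fixed seed of 1. A cluster took the class whose markers had the highest mean log2 fold against all other cells. It needed at least 3 markers at 2-fold or more in at least 10% of its cells. A cluster stayed unnamed where more markers of another class than of its own were among its top 10 genes. It also did where its leading gene and others marked other classes, or where its UMI count was low and its top 10 genes held no marker of its own class. Clusters 26 and 34, with a median of 736 and 719 UMIs, held such a marker and were counted as B-like and NK-like. Classes are named with "-like", since they rest on transcripts alone. Classes with at least 30 cells in every library (10 classes) were tested for transcripts and those with at least 10 cells on average (20 classes) for shares. The smallest class sum held 40 cells. Sums of a class held 294901 to 11623251 UMIs per library, and 5992 to 11180 genes were tested per class.

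Raw counts were summed per library and class. edgeR's quasi-likelihood test, with TMM factors, its low-count filter and robust estimates, was fitted per class on all 8 libraries, so that the groups share an estimate of the spread. Adjusted p-values are Benjamini-Hochberg values within a class and comparison, with a threshold of 0.05. The 6 comparisons were exposed against PBS, both FP doses together against exposed, each dose against exposed, the doses against each other, and both doses against PBS. The standard error of a log2 change is its size over the square root of the F statistic. Shares were tested by the same method on cells per class, with the total of kept cells as the offset. A gene at 0 UMIs in a group was given a bound against a floor of 3 UMIs over the group, and a gene with 1 to 3 UMIs a ratio with its 95% counting interval. These bounds cover counting error alone.

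The 18 gene lists were tested with limma's camera at a preset correlation of 0.01, in the classes written beforehand and where at least 5 members were tested, with Benjamini-Hochberg adjustment over the 57 pairs of a comparison. The lists were type 2 lymphocyte, type 17, type 1 and cytotoxic, T cell activation, naive and recirculating T cell, alternative macrophage activation, interferon response, glucocorticoid response, NF-kB mediators, MHC class II, germinal center and B cell activation, immunoglobulin constant regions, cell cycle, alveolar macrophage identity, lipid and lysosome, dissociation and stress, non-immune and red cell, and neutrophil abundant transcripts. A camera test with an estimated correlation and limma's fry were alternatives. The type 2 and type 17 lists were planned for CD4 T-like cells too, where under 5 members of each were tested. Their other planned classes had too few cells. They were tested in cluster 3, after seeing the data.

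Named genes were, per class, the 2 called genes with the largest rise and the 2 with the largest fall in exposed against PBS and in FP against exposed, and 1 each in the other comparisons. They needed a mean of at least 50 CPM, no overlap between the libraries compared, and a class level of at least 5% of the highest class level, since free RNA can carry less. Predicted gene models, variable segments of immunoglobulin and T cell receptor genes, and hemoglobin, ribosomal, mitochondrial, Xist, Tsix and Y-linked genes were excepted. Genes among the top 10 of a cluster of the class were passed over for the next gene, a rule added after seeing the data. Up to 4 members of a list with the lowest p serve as examples.

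The scripts were tested on simulated counts drawn from the means and library sizes of these libraries, with 200 genes changed per class and 5760 to 10963 genes. The spread of each simulated gene was that of the fitted trend, with no aberrant library and no shift in the mix of cells. For exposed against PBS, edgeR recovered 33.0% to 82.7% of genes changed by 2-fold and 83.9% to 97.9% of those changed by 4-fold, depending on the class, and 0.741% to 6.71% of its calls were unchanged genes. For FP against exposed it recovered 54.1% to 86.7% and 89.8% to 100%, with 0% to 6.21% unchanged genes among its calls. DESeq2 recovered 21.3% to 65.7% and 27.7% to 76.5% of genes changed by 2-fold in these comparisons. Camera called 10 of 10 changed lists and 0 of 200 random lists in each comparison. Simulated genes were drawn independently of each other. This result therefore says nothing about lists whose members vary together, for which the estimated correlation was the alternative. The share test, over 20 simulations, called 57 of 76 classes changed by 4-fold (75.0%) for exposed against PBS and 68 of 79 (86.1%) for FP against exposed, and 7.81% and 11.9% of unchanged classes, whose shares move when others change.

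Alternatives were DESeq2, RLE factors, no low-count filter, at least 500 genes and under 5% mitochondrial UMIs, called doublets kept, Leiden resolution 2, and calls under 5% of the highest class left out. Further ones were only the groups compared in the fit, TMM factors on cell counts, the letter of the library as a block, and each library left out in turn, where the lone library of a group is assumed to vary like the others. Added after seeing the data were clustering without the leading genes, lists without leading genes, the fit without both libraries of low Xist, and tests of 5 further classes in the 6 exposed libraries. Values of 2 genes that passed a test or led a cluster are not reported here, and counts of calls include them. Versions were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1, Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3 and matplotlib 3.10.9.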

Results

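Immune cells of the mouse lung, selected with CD45 magnetic beads after dead cells had been removed, were profiled by droplet single-cell RNA sequencing in 8 libraries. Per the labels, C57Bl/6J pups of both sexes were challenged through the nose from day 3 to 4 of life, 3 times a week for 7 weeks. The challenge was PBS, or 0.5 ug of c-di-GMP with 10 ug each of ovalbumin, house dust mite and the molds Alternaria alternata and Aspergillus fumigatus. Cyclic di-GMP is a bacterial dinucleotide that activates STING. Fluticasone propionate (FP), a glucocorticoid, was given into the peritoneum at 1 or 3 mg/kg over the last 2 weeks. The 4 groups were PBS, exposed without FP (labelled GMPMA), exposed with 1 mg/kg FP (GMPMA_1FP) and exposed with 3 mg/kg FP (GMPMA_3FP), with 2 libraries each, a and b. Each library pooled 2 mouse lungs. The labels do not say whether libraries of a group shared a litter or a day, so p-values measure the spread between these pools.

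The libraries held 6040 to 10050 barcodes, 36003116 to 56389247 UMIs and a median of 3170 to 4324 UMIs per barcode. After filtering, 5587 to 9417 cells remained per library. Counts of the 2 libraries of a group differed by more than sampling noise, with a chi-square of 16.3 to 69.0 per degree of freedom. Xist, the transcript of the inactive X chromosome of female cells, stood at 469 to 735 CPM in 6 libraries, at 88.0 CPM in GMPMA_3FP b and at 0.259 CPM in GMPMA_1FP a. Summed Y-linked transcripts were 241 CPM in GMPMA_1FP a and 90.4 to 154 CPM in the other libraries. From here on, log2 changes carry their standard error and CPM values their SD, with n = 2 libraries per group and n = 4 for both FP doses together.

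The first comparison asked how repeated exposure to c-di-GMP and allergens changed the immune cells of the lung. Natural killer (NK)-like cells made up 47.7% ± 5.91 (SD, n = 2) of cells in the PBS group and 7.18% ± 1.96 in the exposed group, a log2 change of -2.73 ± 0.46 (edgeR, adjusted p = 0.00057). CD8 T-like cells fell as well, from 12.4% ± 1.22 to 4.00% ± 1.02 (log2 -1.63 ± 0.37). Interstitial macrophage-like cells rose from 0.335% ± 0.0968 to 10.1% ± 5.16 (4.90 ± 0.65). This class pooled cluster 13, led by Pf4 and C1qa, and cluster 5, led by Ccl7, Ccl2 and Gpnmb. Cluster 5 had 8 of 12 class markers detected but 0 among its top 10 genes, and 10.5% of its cells were called doublets. Before these were left out, the exposed libraries held 736 and 232 cells of cluster 5 and 228 and 134 of cluster 13. Migratory dendritic-like cells, which express the lymph node homing receptor Ccr7, rose from 0.0416% ± 0.0023 to 0.934% ± 0.255 (4.43 ± 0.51). Cluster 11, left without a name and led by genes that include Mybl1 and Rgs13, rose from 0.0853% ± 0.083 to 3.50% ± 0.711 (5.35 ± 0.65). Cluster 3, also unnamed and led by Il17a, Areg (amphiregulin) and Il1rl1 (the IL-33 receptor), rose from 1.68% ± 0.23 to 8.73% ± 1.33 (2.38 ± 0.38). The class nearest to it by markers was regulatory T cells, with 9 of 11 detected and Ctla4 and Il2ra among its top 10 genes. B-like cells rose from 13.8% ± 3.53 to 36.2% ± 4.20 (1.39 ± 0.38) and neutrophil-like cells from 2.25% ± 0.124 to 6.56% ± 1.27 (1.55 ± 0.50). Plasma-like (2.02 ± 0.49), type 2 innate lymphoid (ILC2)-like (1.56 ± 0.40) and type 2 conventional dendritic (cDC2)-like cells (1.97 ± 0.51) rose too.

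In all, 9 classes were higher and 2 lower among the 20 classes whose shares were tested. All 11 were called in the same direction when cells were clustered without the 10 leading genes of each cluster. For CD8 T-like cells that call rests on a merged T cell cluster of 5396 cells, of which 50.3% were CD8 T-like, and no CD4 T-like class remained. A share falls when others rise. Scaled with TMM factors on cell counts, 3 classes were higher (interstitial macrophage-like, migratory dendritic-like and cluster 11) and 7 lower, NK-like and CD8 T-like cells among them, and the B-like log2 change was 0.04 ± 0.41. The fit without PBS replicate a called 7 classes and lost ILC2-like, cDC2-like, neutrophil-like and plasma-like cells. Without PBS replicate b, B-like (adjusted p = 0.0837) and neutrophil-like cells (0.0919) were lost, and without GMPMA replicate a neutrophil-like (0.0772) and plasma-like cells (0.0551). Clusters set aside as mixed held 14.9% ± 2.22 of cells in the PBS group, 2.28% in the exposed group, 2.61% with 1 mg/kg FP and 1.90% with 3 mg/kg FP.

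**Figure D1:**
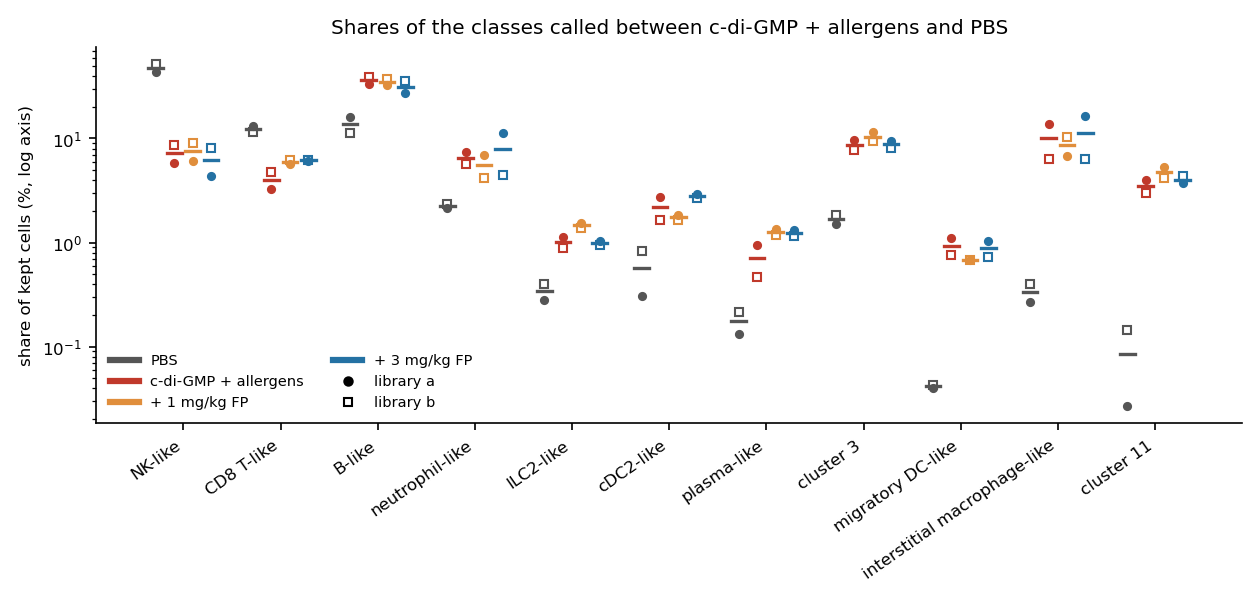
Share of kept cells (%, log axis) of the 11 classes called between the exposed and PBS groups; each point is a library (filled circle a, open square b) and each bar the mean of its group. NK-like cells lie at 47.7% in the PBS group and 7.18% in the exposed group, and the libraries with FP (orange, blue) lie near those without it (red).

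Exposure changed transcripts in each of the 10 classes that could be tested. Over these classes, 15957 gene-class pairs were called, 7741 higher and 8216 lower, of 87243 tested. The alveolar macrophage-like class held the largest number (2556 higher, 2592 lower), followed by B-like cells (1646 and 1715), cluster 3 (839 and 860) and NK-like cells (659 and 895). Cycling cells had 531 and 467, classical monocyte-like cells 430 and 552, CD4 T-like cells 370 and 448, and neutrophil-like cells 292 and 236. CD8 T-like cells had 230 and 232, and nonclassical monocyte-like cells 188 and 219. DESeq2 called 9972 pairs. With a library left out, edgeR called 9291 without PBS a, 10228 without PBS b, 9988 without GMPMA a and 9658 without GMPMA b.

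Genes of alternative activation, the macrophage state driven by IL-4 and IL-13, rose together in alveolar macrophage-like cells. Arg1, which encodes arginase 1, rose from 37.3 ± 48.7 to 4807 ± 175 CPM (log2 7.19 ± 1.36; ENSMUSG00000019987, a protein-coding gene on mm10 chromosome 10 from 24915221 to 24927484). The PBS libraries lay apart, at 2.84 and 71.8 CPM, so the size of this change is loose, and it was called in 9 of 11 alternatives. The chemokine gene Ccl8 rose from 5.52 ± 7.81 to 758 ± 75.2 CPM (7.56 ± 1.20; ENSMUSG00000009185, chromosome 11 from 82115185 to 82116799). Of the 17 tested members of the alternative activation list, 14 rose, 1 (Flt1, -1.22) fell and 2 were not called, with 14 and 1 adjusted over the list alone. Among them were Pdcd1lg2 (3.96 ± 0.22), Fn1 (2.85 ± 0.17), Slc7a2 (1.97 ± 0.14) and Mgl2 (4.43 ± 0.39). The list was called higher by limma's camera test (adjusted p = 1.1e-07), with an adjusted p = 0.227 with an estimated correlation. Its median log2 change was 3.07, or 2.85 with Alox15, which had no PBS count, at its bound. Of 16 members of the lipid and lysosome list, 14 rose, 1 fell and 1 was not called, with 14 and 2 adjusted over the list alone. They included Ctsb (3.03 ± 0.18), Syngr1 (4.02 ± 0.30), Cd63 (2.80 ± 0.23) and Ctsk, which leads a cluster of the class. That list was called higher too (adjusted p = 1.2e-08, and adjusted p = 0.247 with an estimated correlation). Mmp13, a collagenase, had 0 UMIs in the PBS group and 1350 in the exposed group, at least 220-fold higher against a floor of 3 UMIs over the group. It did not meet the naming rule for exposed against PBS, so this bound is given without a call. Of genes that do not lead a cluster, Cyb561a3 (-4.64 ± 0.19) and Fam129a (-4.43 ± 0.30) had the largest falls under the naming rule.

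The alveolar macrophage identity list was called lower, with 4 members higher, 9 lower and 3 not called of 16 (4 and 9 adjusted over the list alone; adjusted p = 3.5e-06, and adjusted p = 0.227 with an estimated correlation). Of its members, 6 lead a cluster of the class. With them left out 3 of 10 were higher and 4 lower, and the list was not called (adjusted p = 0.298). Most PBS cells of this class lay in cluster 22 (led by Ear1, Fabp1 and Krt19) and the exposed cells in cluster 8 (led by Rbp4, Mmp12 and Chil3). These values thus set different clusters against each other. Before called doublets were left out, cluster 22 held 354 and 155 PBS cells. Cluster 8 then held 5 and 10 PBS cells and 396 and 350 exposed ones. Called doublets made up 20.8% of cluster 22 and 4.8% of cluster 8.

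In B-like cells, germinal center and activation genes rose. Of 13 tested members 8 rose, 1 fell and 4 were not called, with the same counts adjusted over the list alone. They included Bcl6, the master regulator of germinal center B cells (1.80 ± 0.14), Cd83 (1.32 ± 0.12), Mef2b (3.35 ± 0.34) and Basp1 (2.63 ± 0.27; its level in the class is 0.848% of the highest class). The list was called higher (adjusted p = 3.5e-06, and adjusted p = 0.227 with an estimated correlation). Plbd1 rose from 9.54 ± 2.15 to 97.1 ± 6.12 CPM (3.36 ± 0.18; ENSMUSG00000030214, protein coding, chromosome 6 from 136612070 to 136661928). Samsn1, an adaptor that restrains B cell activation, rose by 2.93 ± 0.22, while Pafah1b3 (-2.79 ± 0.18) and S100a10 (-1.88 ± 0.16) fell.

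MHC class II genes were called higher in the same cells, with 7 members higher, 0 lower and 7 not called of 14 (7 and 0 adjusted over the list alone; H2-Oa 0.79 ± 0.10, Cd86 0.48 ± 0.10; adjusted p = 0.00041, and adjusted p = 0.489 with an estimated correlation). That call ended with the leading genes Ciita and H2-Oa left out (adjusted p = 0.0507). Of 12 immunoglobulin constant genes 2 were higher and 5 lower (4 and 5 adjusted over the list alone). That list was not called (adjusted p = 0.15). Its median was -0.25, or -0.39 with genes without a PBS count at their bound, its mean 1.27 and the direction of its test down. Ighg1, the IgG1 heavy chain, had 0 UMIs in PBS B-like cells and 892 in exposed ones, at least 96.0-fold higher, at 0.128% of its level in the highest class. The glucocorticoid response list was called lower, with 0 members higher, 5 lower and 11 not called of 16 (0 and 5 adjusted over the list alone; adjusted p = 0.0082, and adjusted p = 0.227 with an estimated correlation). Its members Nfkbia (-1.32 ± 0.11), Tsc22d3 (-1.50 ± 0.21) and Txnip (-1.79 ± 0.26) fell. Most PBS B-like cells lay in cluster 2 and most exposed ones in cluster 0.

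Cluster 3 carried type 2 cytokine transcripts. Il13, which drives mucus production and eosinophil recruitment, rose from 7.86 ± 0.713 to 305 ± 66.3 CPM (5.29 ± 0.90; ENSMUSG00000020383, chromosome 11 from 53631324 to 53634702; called in 6 of 10 alternatives). Il4 rose by 3.77 ± 0.64, and the transcription factor genes Gata3 and Pparg by 1.72 ± 0.13 and 3.44 ± 0.46. Il5, the eosinophil growth factor, had 1 UMI against 140, a ratio of 36.5 (95% interval 6.45 to 1453). The list tests of cluster 3 were added after seeing the data, without the genes that lead the cluster. Of 12 type 2 members 8 rose and 4 were not called (10 adjusted over the list alone). Of 8 type 17 members 4 rose and 4 were not called (6 adjusted over the list alone; Ramp1 1.43 ± 0.18, Cxcr6 2.39 ± 0.36). At Leiden resolution 2 a cluster led by Il17a, with Cxcr6 among its leading genes, held 0 and 0 PBS cells against 100 and 55 exposed ones. A regulatory T-like cluster, with Il2ra and Ctla4 among its leading genes, held 25 and 20 PBS cells against 182 and 99 exposed ones. Changes of state and of the mix of cells, regulatory T-like cells included, were thus not separated in cluster 3. Activation genes rose in 8 of 13, with 5 not called (8 adjusted over the list alone; Cd44 1.17 ± 0.14, Pdcd1 1.65 ± 0.25). Naive and recirculating genes fell in 8 of 12, with 4 not called (10 adjusted over the list alone; Ccr7 -2.48 ± 0.21, Lef1 -1.77 ± 0.28). Type 1 genes were lower in 6, higher in 1 and not called in 7 of 14 (7 lower and 1 higher adjusted over the list alone; Cxcr3 -2.41 ± 0.22, Nkg7 -2.20 ± 0.27). With an estimated correlation none of these lists was called: adjusted p = 0.0903 with an estimated correlation for the type 2, type 17 and type 1 lists, and 0.123 for the others.

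CD8 T-like cells rose in Eomes (1.83 ± 0.21), a transcription factor of memory cells, and in Runx2 (1.83 ± 0.24), and fell in Tuba1a (-1.48 ± 0.16) and Rgcc (-1.35 ± 0.20). Their activation list was called higher, with 4 members higher, 1 lower and 10 not called of 15 (8 and 1 adjusted over the list alone; Cd44 1.08 ± 0.20, Lag3 2.00 ± 0.44; adjusted p = 3.1e-05, and adjusted p = 0.227 with an estimated correlation). In NK-like cells the chemokine receptor gene Cx3cr1 rose from 43.6 ± 8.51 to 133 ± 26.3 CPM (1.62 ± 0.14), and the tubulin genes Tubb4b (-1.19 ± 0.14) and Tuba1a (-1.17 ± 0.16) fell. Their type 1 and cytotoxic list was not called, with 3 members higher and 3 lower of 16 (3 and 4 adjusted over the list alone; adjusted p = 0.97). CD4 T-like cells rose in Socs3, a feedback inhibitor of cytokine signaling (2.07 ± 0.33), and Ndrg3 (1.26 ± 0.15) and fell in Neurl3 (-1.53 ± 0.19) and Rgs10 (-1.29 ± 0.14). Their naive list was called higher, with 6 members higher, 2 lower and 4 not called of 12 (7 and 2 adjusted over the list alone; Tcf7 0.79 ± 0.11, Satb1 0.65 ± 0.11; adjusted p = 0.004, and adjusted p = 0.375 with an estimated correlation). The call ended without PBS b (adjusted p = 0.0511), and with 3 members that lead a cluster left out (4 higher and 2 lower of 9, adjusted p = 0.101).

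The glucocorticoid list was called lower in both T cell classes. In CD4 T-like cells 1 member was higher, 4 lower and 7 not called (1 and 4 adjusted over the list alone; adjusted p = 0.385 with an estimated correlation), and the call ended without PBS b (adjusted p = 0.107) and without GMPMA a (0.269). In CD8 T-like cells 0 members were higher, 1 lower and 13 not called (0 and 3 adjusted over the list alone; adjusted p = 0.227 with an estimated correlation), and the call ended without GMPMA a (adjusted p = 0.147) and at Leiden resolution 2 (0.132). The type 1 list was called lower in CD4 T-like cells, with 3 of 6 members lower and 3 not called (3 adjusted over the list alone; Ccl5 -2.56, Gzma -2.29, Nkg7 -1.96; adjusted p = 0.199 with an estimated correlation). These genes stood there at 0.186%, 0.113% and 0.355% of their highest class, a level that free RNA can give.

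Among monocytes, the classical monocyte-like class rose in Tnip3, an inhibitor of NF-kB signaling, from 7.22 ± 0.949 to 86.6 ± 10.3 CPM (3.53 ± 0.48; called in 9 of 11 alternatives) and in Zfp36l1 from 50.8 ± 1.43 to 238 ± 73.1 CPM (2.18 ± 0.17). Apoe (-1.77 ± 0.32; called in 5 of 11 alternatives) and Tmcc3 (-1.74 ± 0.26) fell. NF-kB mediators were called higher there, with 5 members higher and 11 not called of 16 (5 higher and 2 lower adjusted over the list alone; Tnfaip3 1.14 ± 0.18, Il6 3.56 ± 0.51; adjusted p = 0.00048, and adjusted p = 0.227 with an estimated correlation). The lipid and lysosome list had 1 member higher and 2 lower of 13 and was not called; its median was -0.04, its mean 0.46 and the direction of its test down. In nonclassical monocyte-like cells the adhesion gene Pecam1 (2.05 ± 0.25) and Etv3 (1.85 ± 0.33) rose, and Edf1 (-1.29 ± 0.21) and Hsd11b1, which activates glucocorticoids (-1.28 ± 0.32; called in 8 of 11 alternatives), fell. Their MHC class II list was called higher, with 4 members higher and 6 not called of 10 (4 adjusted over the list alone; H2-Aa 1.66 ± 0.15, H2-Ab1 1.83 ± 0.17; adjusted p = 2.4e-12, and adjusted p = 0.199 with an estimated correlation). With called doublets kept its direction turned to down and it was not called (adjusted p = 0.877).

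In neutrophil-like cells Prnp had 1 UMI against 149, a ratio of 45.4 (95% interval 8.02 to 1803), and Col15a1 had 0 against 166, at least 16.8-fold higher. Med31 (-1.76 ± 0.30; called in 8 of 11 alternatives and of the same sign in 10) and the cell cycle inhibitor gene Cdkn2d (-1.75 ± 0.27; called in 10) fell. Most PBS neutrophil-like cells lay in cluster 14 and the exposed ones in clusters 12 and 14. Their MHC class II list was called higher, with 3 of 10 members higher and 7 not called (4 adjusted over the list alone; Cd74 1.44 ± 0.23; adjusted p = 0.0044, and adjusted p = 0.325 with an estimated correlation). With called doublets kept (adjusted p = 0.812) and at Leiden resolution 2 (0.136) it too turned to down and was not called. The NF-kB list had 4 of 19 members higher and 15 not called (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.0015, and adjusted p = 0.385 with an estimated correlation), and its members Ptgs2, Cxcl2 and Il1rn lead cluster 12. The alternative activation list was also called higher in nonclassical monocyte-like (3 of 6 higher, 3 not called), neutrophil-like (3 of 9 higher, 6 not called) and classical monocyte-like cells (2 of 9 higher, 7 not called). Adjusted over the list alone, 3, 6 and 2 were higher, with adjusted p = 0.199, 0.227 and 0.199 with an estimated correlation. Retnla, one of its members, had 0 UMIs against 13 and 50 in nonclassical monocyte-like and neutrophil-like cells, at least 10.7-fold and 5.07-fold higher, at 0.701% and 1.57% of its level in the highest class.

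The interferon response list went different ways among classes. In alveolar macrophage-like cells 13 of 28 members rose, 1 fell and 14 were not called (13 and 1 adjusted over the list alone), including Oas1a (2.78 ± 0.45), Ifi204 (2.95 ± 0.33) and Usp18 (3.11 ± 0.49). The list was called higher (adjusted p = 0.0123, and adjusted p = 0.73 with an estimated correlation), but not with called doublets kept (adjusted p = 0.146). In classical monocyte-like cells 8 of 27 fell and 19 were not called (8 adjusted over the list alone; Rtp4 -0.97 ± 0.17, Irf7 -0.70 ± 0.14, Ifit3 -1.31 ± 0.24). In CD4 T-like cells 4 of 20 fell and 16 were not called (4 adjusted over the list alone; Isg15 -1.51 ± 0.27, Bst2 -0.89 ± 0.18). Both lists were called lower, with adjusted p = 0.489 and 0.304 with an estimated correlation. The former was lost without PBS b (adjusted p = 0.0634) and without GMPMA b (0.0569), the latter without PBS a (0.0752) and at Leiden resolution 2 (0.0898). In CD8 T-like cells the list was called higher (adjusted p = 0.0489, and adjusted p = 0.768 with an estimated correlation) with 0 of 25 members called by edgeR and 2 adjusted over the list alone. That call ended in 5 of 10 alternatives: without PBS b (0.107), GMPMA a (0.269, direction down), GMPMA_3FP a (0.0991) or GMPMA_3FP b (0.127) and with called doublets kept (0.15).

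Genes of dissociation and stress were called higher in nonclassical monocyte-like (5 higher, 11 not called), classical monocyte-like (6 higher, 10 not called) and alveolar macrophage-like cells (9 higher, 2 lower, 5 not called). Adjusted over the list alone there were 6 and 0, 6 and 2, and 9 and 4, with adjusted p = 0.199, 0.349 and 0.559 with an estimated correlation. With called doublets kept the first (adjusted p = 0.0684) and the last (0.0698) were not called, and the last was also lost without PBS a (0.0816) and GMPMA b (0.0953). The cell cycle list was not called in any of 4 classes (7 of 16 members lower and 1 higher in alveolar macrophage-like cells, adjusted p = 0.0939). Transcripts abundant in neutrophils were called lower in alveolar macrophage-like cells, with 6 of 8 lower and 2 not called (8 adjusted over the list alone; adjusted p = 0.375 with an estimated correlation). They were called higher in classical monocyte-like cells with 0 of 6 members called by edgeR, also when adjusted over the list alone (adjusted p = 0.255 with an estimated correlation), and not without PBS a (adjusted p = 0.0520). Non-immune and red cell transcripts made up 0.000497% to 0.0311% of UMIs per library. Counts summed over all cells of a library, which also carry the shifts in shares, had 2880 genes higher and 2785 lower. Timp1 (6.23 ± 0.75) and Ccl24 (6.65 ± 1.44) were among the largest, named after their values were seen.

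The second comparison asked what 2 weeks of FP changed in exposed lungs, and few transcripts passed the test. In alveolar macrophage-like cells Pdgfa, which encodes a growth factor for fibroblasts, fell from 185 ± 13.8 CPM without FP to 67.4 ± 10.0 CPM with FP (-1.45 ± 0.12, adjusted p = 2.8e-05; ENSMUSG00000025856, protein coding, chromosome 5 from 138976014 to 138997370). The PBS group had 1.95 ± 1.15 CPM. In classical monocyte-like cells Thbs1, which encodes the matrix protein thrombospondin 1, fell from 884 ± 27.7 to 456 ± 56.7 CPM (-0.95 ± 0.10, adjusted p = 5.9e-07; ENSMUSG00000040152, chromosome 2 from 118111876 to 118127133). The PBS level of Thbs1 was 1062 ± 114 CPM, above that of the exposed group. The interferon-induced genes Rtp4 (0.88 ± 0.16) and Gbp3 (0.86 ± 0.17) rose in the same cells. Rtp4 stood at 113 ± 20.5 CPM in the PBS group, 59.3 ± 7.71 without FP and 107 ± 9.73 with it. Gbp3 stood at 58.6 ± 4.97, 45.9 ± 6.88 and 81.3 ± 15.4 CPM in that order. In nonclassical monocyte-like cells Crip1 (-0.69 ± 0.10) and the immediate early gene Jun (-0.71 ± 0.14) fell. Crip1 stood at 1030 ± 22.2 CPM in the PBS group, 1577 ± 41.8 without FP and 975 ± 121 with it. Jun stood at 308 ± 78.7, 504 ± 15.7 and 308 ± 30.3 CPM in that order, so both lay near the PBS level with FP. Further calls were named after their values were seen. They included Vegfa (-1.90 ± 0.23; 3.4% of its level in the highest class) and Acpp (-1.37 ± 0.21) in alveolar macrophage-like cells, and the heat shock gene Hsph1 (-0.74 ± 0.10) in B-like cells. Nonclassical monocyte-like cells added Egr1 (-1.07 ± 0.23; 0.787% of the highest class), Mat2a (-0.66 ± 0.14) and Nceh1 (-2.90 ± 0.65). Nceh1 had 0 and 2.09 CPM at 1 mg/kg, 8.85 and 20.7 at 3 mg/kg and 28.6 and 37.7 without FP, and was not called at 3 mg/kg alone (-1.05 ± 0.55).

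For both doses together edgeR made 13 calls, 3 higher and 10 lower. CD4 T-like, CD8 T-like, NK-like, cycling and neutrophil-like cells and cluster 3 had 0, with 412, 410, 477, 572, 139 and 389 genes at an unadjusted p under 0.05; DESeq2 called 1 gene in NK-like cells and 0 in the other 5. Pdgfa and Thbs1 were called in 11 of 11 alternatives, Crip1 and Vegfa in 10, Rtp4 and Jun in 8, Hsph1, Egr1 and Mat2a in 7, Nceh1 in 6 and Acpp and Gbp3 in 4. DESeq2 called 8 pairs over all classes, and edgeR 21 without GMPMA_1FP a, 26 without GMPMA_1FP b, 43 without GMPMA_3FP a and 38 without GMPMA_3FP b. Without both libraries of low Xist, a fit chosen after seeing the data that leaves 1 library per dose, 121 pairs were called (69 higher, 52 lower), 11 of them among the 13. Over all cells edgeR called 0 genes, with 530 at an unadjusted p under 0.05, and DESeq2 called 13 (12 higher, 1 lower). For 1 mg/kg alone over all cells edgeR called 1 gene and DESeq2 54 (49 higher, 5 lower). For 3 mg/kg alone they called 0 and 2. With both doses together, shares of cell classes differed in 0 of 20 classes (edgeR; 1 at an unadjusted p under 0.05). The cycling class changed most, by 0.96 ± 0.36 (adjusted p = 0.476).

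**Figure D2:**
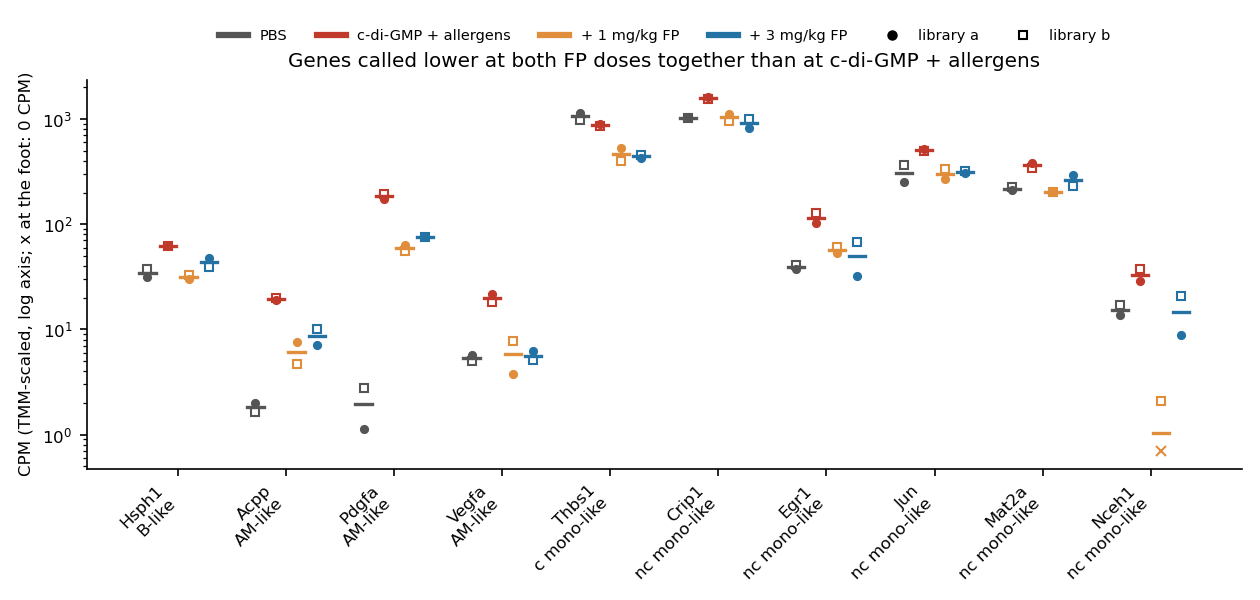
Level (CPM, TMM-scaled, log axis; a cross at the foot marks 0 CPM) of the 10 genes called lower in exposed libraries with FP than in those without it, in the class where each was called (AM, alveolar macrophage; c mono and nc mono, classical and nonclassical monocyte); each point is a library and each bar the mean of its group. Pdgfa lies at 185 CPM without FP and at 67.4 CPM with it, and at 1.95 CPM in the PBS group.

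Genes of the type 2 response did not pass the test with FP. In cluster 3, Il13 stood at 305 ± 66.3 CPM without FP and 283 ± 105 with it (-0.12 ± 0.38). Il5 had a log2 change of 0.42 ± 0.36 and Il4 of -0.35 ± 0.26. Of 15 tested type 2 members 0 were called by edgeR, also when adjusted over the list alone (adjusted p of the list 0.15; fry 0.81). In alveolar macrophage-like cells Arg1 stood at 4807 ± 175 and 3458 ± 997 CPM (-0.51 ± 0.85). Of 17 members of the alternative activation list 0 were called by edgeR, also when adjusted over the list alone (adjusted p of the list 0.71; its median was -0.08 and its mean 0.07). The list was called lower with FP in classical monocyte-like and neutrophil-like cells, with 0 of 9 members called by edgeR in each, also when adjusted over the list alone. Its medians there were -0.50 and -0.52 (adjusted p = 0.0108 and adjusted p = 0.00595, or adjusted p = 0.363 and adjusted p = 0.577 with an estimated correlation). Both calls ended without GMPMA a (adjusted p = 0.762 and 0.753), and that in neutrophil-like cells was kept in 5 of 10 alternatives.

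Single textbook targets of the glucocorticoid receptor did not pass the test either. Over 9 classes, 0 of 141 tests of members of the glucocorticoid list were called by edgeR, and 67 changes were positive. Tsc22d3, which encodes the mediator GILZ, stood at 0.40 ± 0.18 in B-like cells (edgeR, unadjusted p = 0.0504), 0.24 ± 0.12 in CD4 T-like cells (0.0463) and 0.44 ± 0.15 in classical monocyte-like cells (0.00672). Its change was positive in each class tested, the lowest of these 9 at 0.03 ± 0.28 in neutrophil-like cells, and 0.25 ± 0.19 over all cells. Classes of the same libraries are not independent, and Fkbp5 and Per1 had changes of both signs. The glucocorticoid list was called higher in B-like cells at 3 mg/kg against exposed, with 0 of 16 members called by edgeR or adjusted over the list alone (median 0.21, camera adjusted p = 0.0228, and adjusted p = 0.343 with an estimated correlation). At 3 against 1 mg/kg the list was called higher there with 0 of 16 called and 3 adjusted over the list alone (median 0.12; adjusted p = 0.0150, and adjusted p = 0.500 with an estimated correlation). These calls ended without GMPMA b (adjusted p = 0.195) and without GMPMA_1FP b (0.531), in that order. Tests added after seeing the data called the list lower with FP in cluster 3 (adjusted p = 0.0155, and adjusted p = 0.232 with an estimated correlation) and in cDC2-like cells (adjusted p = 0.00026, and adjusted p = 0.413 with an estimated correlation). In cluster 3 0 of 17 members were called or adjusted over the list alone, and in cDC2-like cells 0 of 19, with 1 adjusted over the list alone. On simulated data of this comparison, edgeR recovered 54.1% to 86.7% of genes changed by 2-fold, depending on the class. Simulated genes had the spread of a fitted trend and no aberrant library, so this is not the recovery of a given glucocorticoid target. The standard error of Fkbp5, for example, ran from 0.12 in cluster 3 to 0.46 in nonclassical monocyte-like cells.

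Interferon response genes were called higher as a list with FP in 7 of 8 planned classes. The median log2 change of its members was 0.52 in nonclassical monocyte-like, 0.42 in CD8 T-like, 0.36 in neutrophil-like and 0.32 in CD4 T-like cells. It was 0.31 in alveolar macrophage-like, 0.22 in classical monocyte-like and 0.21 in B-like cells, and the list was not called in NK-like cells (0.10). Rtp4 passed the test in classical monocyte-like cells. Adjusted over the list alone, 3 members were higher in classical monocyte-like, 3 in nonclassical monocyte-like, 3 in CD8 T-like, 2 in CD4 T-like and 0 in B-like, alveolar macrophage-like and neutrophil-like cells. Other members included Ifit3 in CD8 T-like cells (1.39 ± 0.29, not called) and Gbp2 in classical monocyte-like cells (0.75 ± 0.19, not called). With an estimated correlation no class was called (adjusted p = 0.297 to adjusted p = 0.577 with an estimated correlation). The call ended without GMPMA b in B-like (adjusted p = 0.801), CD8 T-like (0.801), alveolar macrophage-like (0.553), neutrophil-like (0.4) and classical monocyte-like cells (0.177). It also ended without GMPMA_3FP a in B-like, alveolar macrophage-like (both 0.273) and neutrophil-like cells (0.174). At 1 mg/kg alone the list was called higher in 5 of these classes, but not in alveolar macrophage-like (adjusted p = 0.908) or B-like cells (0.835), and at 3 mg/kg in all 7, with 0 of these calls left at either dose with an estimated correlation. Without GMPMA b the call at 1 mg/kg was lost in neutrophil-like cells (adjusted p = 0.889), and in CD8 T-like (0.716) and classical monocyte-like cells (0.752) it turned to down. The last 2 were also lost without GMPMA_1FP b (adjusted p = 0.130 and 0.0654). At 3 mg/kg the call was lost without GMPMA b in CD8 T-like (adjusted p = 0.216) and neutrophil-like cells (0.0816), and in CD4 T-like cells at Leiden resolution 2 (0.209). Without GMPMA_3FP a it was lost in alveolar macrophage-like (adjusted p = 0.120) and B-like cells (0.0983) and turned to down in neutrophil-like cells (0.737). It was called higher at 3 than at 1 mg/kg in alveolar macrophage-like (adjusted p = 8.0e-12), B-like (2.7e-11) and classical monocyte-like cells (2.3e-06). Of these calls between the doses 0 members passed edgeR, and 2, 0 and 2 did adjusted over the list alone (adjusted p = 0.636 in each class with an estimated correlation). The calls in alveolar macrophage-like (adjusted p = 0.180) and B-like cells (0.119) ended without GMPMA_3FP a.

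**Figure D3:**
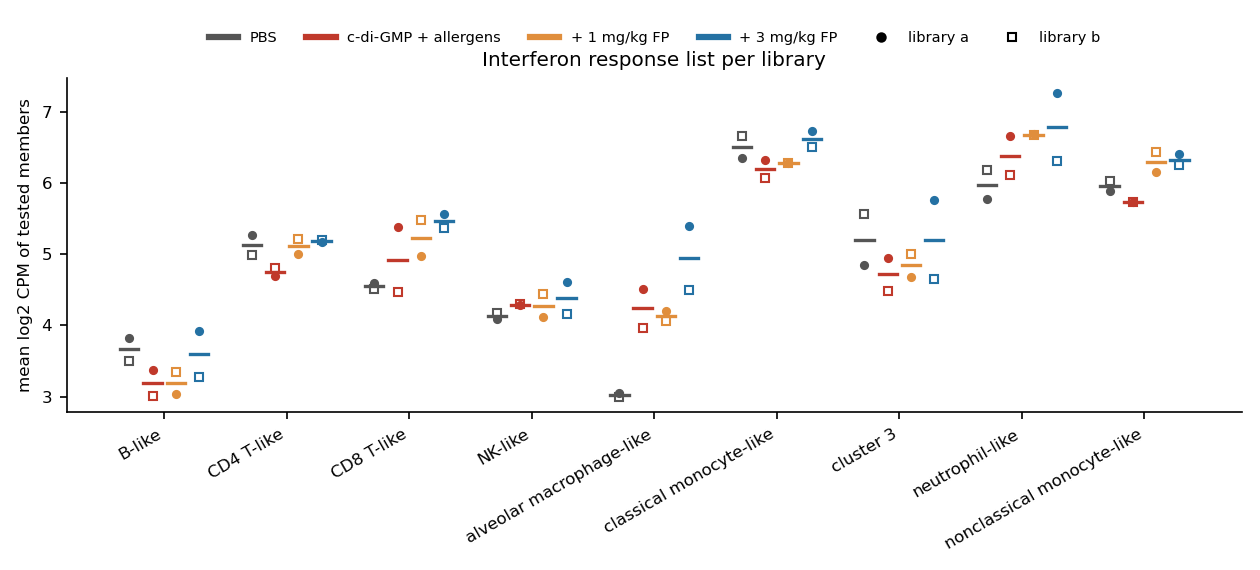
Mean log2 CPM of the tested members of the interferon response list in each class; each point is a library (filled circle a, open square b) and each bar the mean of its group. In alveolar macrophage-like cells the libraries lie at 3.05 and 3.00 in the PBS group, 4.52 and 3.96 in the exposed group, and 5.40 in GMPMA_3FP a.

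Of the other lists, NF-kB mediators were called lower with FP in alveolar macrophage-like cells, with 0 of 20 members called by edgeR and 2 lower adjusted over the list alone (adjusted p = 0.00011, and adjusted p = 0.363 with an estimated correlation). These were Il6 (-1.66 ± 0.32, at 0.302% of the highest class) and Ccl4 (-0.59 ± 0.13, at 1.08%), and the call ended without GMPMA a (adjusted p = 0.423). The mean log2 CPM of this list in alveolar macrophage-like cells was 5.69 without FP, 5.23 at 1 mg/kg and 5.73 at 3 mg/kg. At 1 mg/kg alone it was called lower (camera, adjusted p = 1.5e-07), and at 3 mg/kg alone it was not called. It was called higher at 3 than at 1 mg/kg (camera, adjusted p = 2.3e-06). With an estimated correlation neither of these calls was left. Stress genes were called lower in nonclassical monocyte-like cells, with 2 of 16 lower and 14 not called (4 adjusted over the list alone; adjusted p = 2.2e-07, and adjusted p = 0.297 with an estimated correlation). They were also called lower in CD4 T-like (adjusted p = 0.00038; 0 of 14 called and 1 adjusted over the list alone) and alveolar macrophage-like cells (adjusted p = 0.0072; 0 of 16 called or adjusted over the list alone). Both calls ended without GMPMA b (adjusted p = 0.0756 and 0.899), and with an estimated correlation (adjusted p = 0.577 in each). In alveolar macrophage-like cells the mean log2 CPM of the stress list was 7.99 without FP, 7.74 at 1 mg/kg and 7.94 at 3 mg/kg. At 1 mg/kg alone it was called lower there (camera, adjusted p = 0.0022), and at 3 mg/kg alone it was not called. In CD8 T-like cells the type 1 and cytotoxic list was called higher, with 0 of 16 members called by edgeR or adjusted over the list alone (median 0.55; adjusted p = 0.0004, and adjusted p = 0.577 with an estimated correlation). That call ended without GMPMA a (adjusted p = 0.094). In B-like cells the immunoglobulin constant list was called higher, with 0 of 12 members called by edgeR or adjusted over the list alone (median 0.14; adjusted p = 0.00038, and adjusted p = 0.577 with an estimated correlation), and not without GMPMA b (adjusted p = 0.201). The CD8 T-like class pooled cluster 6, with Lef1 and Dapl1 among its leading genes, and cluster 17, led by Gzmk. Before called doublets were left out, libraries a and b held 38 and 63 cells of cluster 17 without FP, 128 and 124 at 1 mg/kg and 215 and 66 at 3 mg/kg. Cluster 6 held 177 and 182, 250 and 284, and 184 and 277. Changes of state and of this mix were thus not separated in the CD8 T-like lists. The naive list was called lower in CD4 T-like (adjusted p = 0.0183) and CD8 T-like cells (0.00066), with 0 of 12 members called by edgeR or adjusted over the list alone in each. Also called lower were transcripts abundant in neutrophils in classical monocyte-like cells (adjusted p = 0.00126; 0 of 6 called and 1 adjusted over the list alone) and NF-kB mediators in neutrophil-like cells (adjusted p = 0.0247; 0 of 19 called or adjusted over the list alone). These 4 calls ended without GMPMA a (adjusted p = 0.142, 0.127, 0.0885 and 0.636) and with an estimated correlation (adjusted p = 0.577, 0.577, 0.297 and 0.577). In all, 19 of 57 pairs of a list and a class were called with FP and 27 with exposure, and none of either kind with an estimated correlation.

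The doses were also compared apart. Pdgfa fell at both doses (-1.62 ± 0.14 at 1 mg/kg and -1.29 ± 0.14 at 3 mg/kg), as did Thbs1 (-0.91 ± 0.12 and -0.99 ± 0.12) and Crip1 (-0.60 ± 0.12 and -0.77 ± 0.12). At 1 mg/kg the chemokine gene Ccl4 (-1.04 ± 0.16; 1.08% of the highest class) and Ms4a7 (-0.95 ± 0.15) fell in alveolar macrophage-like cells and Il1b (-0.64 ± 0.11) in classical monocyte-like cells. Ctla4 (3.92 ± 0.65) was higher in classical monocyte-like cells, at 0.622% of its level in the highest class. With 1 mg/kg FP 15 pairs were called (4 higher, 11 lower) and with 3 mg/kg FP 6 (2 higher, 4 lower). Between the doses 3 pairs were called. Ms4a6c (1.38 ± 0.16) and Pf4 (1.00 ± 0.15) were higher at 3 than at 1 mg/kg in alveolar macrophage-like cells, and Egr3 (-2.33 ± 0.33; 2.46% of the highest class) was lower in cycling cells. Pf4 and Ms4a7 are among the markers fixed for interstitial macrophage-like cells, and stood here at 40.4% and 41.5% of their level in the highest class. A change within alveolar macrophage-like cells and a shift in the mix of cells were not separated for them. Of the 11 alternatives, Ccl4 and Pf4 were called in 5, Ms4a7 in 6, Ctla4 in 7, Il1b in 8 and Ms4a6c and Egr3 in 10. Without both libraries of low Xist these counts were 142, 220 and 147. That fit leaves 1 library per dose, and its spread is assumed to be that of the other groups, so these counts are no replicated test. Without GMPMA_3FP b alone, with 1 library left at 3 mg/kg, they were 53, 121 and 153, and without GMPMA b the count at 1 mg/kg was 8. Class shares differed in 0 of 20 classes in each of these comparisons (edgeR; 2, 0 and 0 at an unadjusted p under 0.05).

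Cell classes with too few PBS cells were tested in the 6 exposed libraries, a test added after seeing the data. In ILC2-like cells Rgs16 (-2.32 ± 0.28), a regulator of G protein signaling, and Nrgn (-1.46 ± 0.26) fell with FP. In cDC2-like cells the replication gene Pclaf rose (1.21 ± 0.16), and in migratory dendritic-like cells F10 (-2.88 ± 0.46; 4.64% of the highest class) and Mpeg1 (-1.66 ± 0.28; 3.67%) fell. Interstitial macrophage-like cells and cluster 11 had 0 calls with edgeR and 278 and 395 genes at an unadjusted p under 0.05. Cell cycle genes were called higher as a list in cDC2-like cells, with 1 of 16 members called and 7 adjusted over the list alone (Mki67 1.02 ± 0.21, not called; adjusted p = 1.6e-18, and adjusted p = 0.413 with an estimated correlation). The 5 calls over these classes became 9 without GMPMA_3FP a and 29 without GMPMA_1FP b.

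The last comparison set both FP groups against PBS, to see how far exposed lungs with FP differed from unexposed ones. NK-like cells were lower (-2.79 ± 0.36), and cluster 3 (2.51 ± 0.36), cluster 11 (5.66 ± 0.63), interstitial macrophage-like (4.88 ± 0.63) and plasma-like cells (2.83 ± 0.46) were higher. Plbd1 in B-like cells (3.23 ± 0.17), Cx3cr1 in NK-like cells (1.71 ± 0.12), Eomes in CD8 T-like cells (1.95 ± 0.18) and Pecam1 in nonclassical monocyte-like cells (2.00 ± 0.21) were higher. Lyz2, which encodes lysozyme, was lower in nonclassical monocyte-like cells (-1.52 ± 0.09). In all, 19577 pairs were called, 9305 higher and 10272 lower, and 9 classes had a higher and 2 a lower share, or 5 and 8 with TMM factors on cell counts. The count of pairs was 10580 without PBS a, 11483 without PBS b, 11751 with DESeq2 and 29535 with called doublets kept, where clusters otherwise set aside as mixed enter the classes.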

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

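All tests of explanations in this part were chosen after the result they test was seen. The changes between exposed and PBS libraries went opposite ways in pairs of classes for the 2 gene lists called in both directions in the planned tests, and the differences themselves were not tested. Lists not called in both classes, or called in cluster 3 alone, were not flagged, though some moved apart too. The naive list, for example, was higher by 0.23 in CD4 T-like cells and lower (-1.46) in cluster 3. The mean log2 CPM of the interferon response list was higher by 1.22 in alveolar macrophage-like cells and lower (-0.38) in CD4 T-like cells, with every exposed library above, or below, both PBS libraries, a difference of 1.59. Transcripts abundant in neutrophils were higher by 1.03 in classical monocyte-like cells and lower (-1.70) in alveolar macrophage-like cells in the same sense, a difference of 2.73.

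The genes that rose in alveolar macrophage-like cells with exposure may reflect a change of state, or other cells counted in the class. Free RNA from the other cells of the library would follow the sum over all cells, but 82.0% of the 2556 genes that rose lay above that sum, which argues against it as the main source. A mixture with another class cannot exceed its source. Of the genes that rose, 518 (20.3%) lay above every one of 19 other classes, between the bounds of 10% and 25% set for and against a mixture, so this explanation stays open. The median level of the genes that rose was 104% of that in interstitial macrophage-like cells, the class nearest at hand as a source.

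The lower share of NK-like cells with exposure may be a loss of these cells or dilution by incoming ones. Dilution lowers all classes that did not rise by the same factor. The ratio of NK-like cells to 4 such classes (CD4 T-like, classical and nonclassical monocyte-like and plasmacytoid dendritic-like cells) was taken. Its log2 value fell by 2.02, beyond the pooled SD of 0.213, from 1.40 and 1.77 in the PBS libraries to -0.33 and -0.54 in the exposed ones. CD8 T-like cells, whose share fell too, and other classes not called higher were not in this ratio. Its fall argues against dilution as the whole cause, provided that the 4 classes gained no cells themselves. With called doublets and mixed clusters kept, the NK-like change was -2.50 ± 0.49 (edgeR, adjusted p = 7.5e-06), which argues against loss to the mixed clusters. A biological loss and an effect of dissociation or selection on these cells stay open.

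Few genes passed the test with FP. An aberrant library that hides the response would raise the count of 13 when left out, and the count rose without each FP library, to 21, 26, 38 and 43. The highest was without GMPMA_3FP a. The count also rose without each PBS library and each exposed library without FP, so a rise is not particular to the FP libraries. The highest count lay between the bounds set for and against this explanation, so a single library as the cause stays open. Without both libraries of low Xist, which are both FP libraries, the count went from 13 to 121. An effect of the pair stays open, since 1 library per dose is left in that fit and its spread is assumed. For 3 mg/kg alone the count went from 6 to 121 without GMPMA_3FP b, so an effect of that library stays open there. A weak glucocorticoid receptor signal in these cells at harvest stays open too. For both doses together 0 of 141 tests of members of the glucocorticoid list were called by edgeR, but a signal under the reach of 2 libraries per group would look the same. The change of Tsc22d3 was positive in each class tested, though not called. In B-like cells the list was called higher at 3 mg/kg against exposed (adjusted p = 0.0228, and adjusted p = 0.343 with an estimated correlation) with 0 of 16 members called, and not without GMPMA b (adjusted p = 0.195). In tests added after seeing the data it was called lower with FP in cluster 3 and cDC2-like cells, so these calls decide nothing. The labels do not give the hours between the last dose and harvest.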

How the results depend on the processing

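Fits without both libraries of low Xist, tests in 6 libraries, clustering and lists without leading genes, list tests in clusters 3 and 11 and the doublet rule were chosen after the data were seen; the other alternatives were planned. Over all alternatives, 237 of 333 counts lay within 1.5 times the count as reported and 96 did not; the causes were not tested, unless the construction shows them. DESeq2, which recovered fewer simulated genes, called 9972 pairs for exposed against PBS (15957 with edgeR), 8 for FP against exposed (13), 15 between the doses (3), 11751 for FP against PBS (19577) and 13 genes over all cells for FP (0). Without a low-count filter the count became 142 for FP, 180 for 1 mg/kg, 130 for 3 mg/kg and 180 between the doses. With only the groups compared in the fit it was 28 for 1 mg/kg and 16 for 3 mg/kg. Between the doses it was 5 with called doublets kept and 7 with the stricter cell filter, and for FP against PBS 29535 with called doublets kept. RLE factors and Leiden resolution 2 moved no count of calls beyond 1.5 times.

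Of 57 pairs of a list and a class, 27, 19, 26, 18, 14 and 24 were called in the 6 comparisons (exposed against PBS, FP, 1 mg/kg and 3 mg/kg against exposed, between the doses, FP against PBS). An estimated correlation left 0 in all 6. Fry, which does not compare a list with other genes, left 16 for exposed against PBS, 12 for FP against PBS and 0 in the other 4. With called doublets kept, 28 were called for 3 mg/kg and 26 between the doses, of 66 pairs tested there.

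With each library left out in turn, counts ranged from 9291 to 17634 for exposed against PBS, 15 to 43 for FP, 8 to 53 for 1 mg/kg, 9 to 121 for 3 mg/kg, 3 to 153 between the doses and 10580 to 18904 for FP against PBS. Over all cells they ranged from 2886 to 6178 for exposed against PBS and 0 to 1 for FP, and classes with a changed share from 7 to 12 (11 with all libraries). List calls ranged from 16 to 27 for 1 mg/kg and 17 to 25 between the doses, of 58 or 59 pairs tested. Without both libraries of low Xist, 121, 142, 220 and 147 pairs were called for FP, 1 mg/kg, 3 mg/kg and between the doses, of which 11, 10, 5 and 3 were among those called with all libraries. Each dose is then a single library whose spread is assumed, and the count between the doses sets 1 library against 1. List calls were then 28 for 1 mg/kg and 25 between the doses. In the 6 exposed libraries, 5, 4, 0 and 4 calls for FP, 1 mg/kg, 3 mg/kg and between the doses became 9 to 29, 8 to 46, 5 to 15 and 14 to 26 with a library left out.

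The letters a and b were not used as pairs. The labels do not say whether they mark a shared litter or day, which stays open, and deviations of the same letter in different groups correlated from -0.18 to 0.73 over all cells, above 0.1 in 3 of 6 pairs of groups, and in 0 to 2 of 6 pairs within a class. The share of cluster 31 was higher in library a than in b in each group with exposure, and lower in a in the PBS group. With the letter as a replicate block, 12 pairs were called between the doses (3 without it), and no other count of calls moved by over 1.5 times. Depth limits genes near the floor: the smallest class sum held 294901 UMIs, so that 1 UMI there stands for several CPM.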

Other observations

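In cycling cells with exposure Il1rl1, the IL-33 receptor gene, rose from 9.50 ± 1.81 to 174 ± 22.3 CPM, and the transcription factor gene Hlf had 1 UMI against 204, a ratio of 377 (95% interval 66.9 to 14961). Txnip (-3.00 ± 0.29), a glucose-responsive inhibitor of thioredoxin, and the NK receptor gene Klrd1 (-1.82 ± 0.36; called in 7 of 11 alternatives) fell. The cycling class pools cell types, so a change of state and a change in which cells cycle were not separated. In cluster 3 the vitamin D receptor gene Vdr rose from 3.56 ± 0.877 to 87.3 ± 0.872 CPM (4.64 ± 0.42), and Ms4a4b (-2.48 ± 0.12) and Gramd3 (-2.46 ± 0.17) fell. Il21, a cytokine of follicular helper T cells, had 1 UMI there against 128, a ratio of 33.4 (95% interval 5.89 to 1329). In alveolar macrophage-like cells Nos2, the inducible nitric oxide synthase gene, had 0 UMIs in the PBS group against 240, at least 39.1-fold higher, and the chitinase-like gene Chil4 had 2 against 475, a ratio of 116 (95% interval 31.9 to 961). Genes higher or lower with FP against PBS included Tnip3 in classical monocyte-like cells (3.15 ± 0.45), Socs3 in CD4 T-like cells (1.89 ± 0.29), Cdkn2d in neutrophil-like cells (-1.85 ± 0.23) and Pafah1b3 in B-like cells (-2.47 ± 0.15).

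List tests of further classes with FP were added after the data were seen. Interferon response genes were called higher in cluster 3 (adjusted p = 0.00012), cDC2-like (0.00012), interstitial macrophage-like (4.7e-05) and ILC2-like cells (0.0095), with 0 members called by edgeR or adjusted over the list alone and adjusted p = 0.639 to adjusted p = 0.788 with an estimated correlation. The cell cycle list was called higher in cluster 3 with 0 of 14 members called and 1 adjusted over the list alone (median log2 change 0.52; adjusted p = 1.8e-09, and adjusted p = 0.232 with an estimated correlation). In cluster 11 it was called higher with 0 of 16 called and 2 adjusted over the list alone (median 0.15; adjusted p = 1.1e-05, and adjusted p = 0.413 with an estimated correlation). Without both libraries of low Xist, the interferon list was called higher with FP in all 8 planned classes (adjusted p = 2.4e-17 to 0.0126), with 1 library left per dose, and in 0 of them with an estimated correlation (adjusted p = 0.571 in each).

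At 1 mg/kg in the 6 exposed libraries, cDC2-like cells fell in Rab7b (-1.48 ± 0.20) and Grasp (-1.71 ± 0.23). Between the doses the 4 calls in migratory dendritic-like cells were the T cell transcripts Icos (-2.93 ± 0.50), Trbc1 (-5.13 ± 0.78), Maf (-3.37 ± 0.48) and Emb (-3.07 ± 0.45), at 3.11%, 5.77%, 3.01% and 3.65% of their level in the highest class. Cluster 31, which holds cells with the epithelial transcript Sftpc and the endothelial transcript Cldn5, made up 0.147% ± 0.057 of cells in the PBS group and 0.724% ± 0.996 in the exposed group. Its share in libraries a and b was 0.107% and 0.187% in the PBS group and 1.43% and 0.0193% in the exposed group. It was 0.484% and 0.0454% at 1 mg/kg and 0.927% and 0.0926% at 3 mg/kg. Library a thus lay above b in each group with exposure, and the mean of the exposed group rests on library a. The covariance of FP and exposure changes was taken across genes, which are not independent replicates. That of 20 simulations with the same shared libraries, and no effect of exposure or FP, was subtracted. The remaining covariance was set against the variance of the exposure changes. It gave a share of the exposure change reversed with FP of -7.92% in CD8 T-like cells to 9.30% in CD4 T-like cells. With the exposed libraries split between both changes it gave -3.47% and 10.7% there, and in cycling cells its sign changed, from 1.28% to -0.96%.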
